A study of Arabidopsis thaliana with 28 samples.

How the data were processed

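RNA from whole Arabidopsis seedlings was sequenced in 28 samples that the labels place in 10 groups. Per the labels' protocols, seedlings grew for 7 days on plates and were then kept in liquid medium for 3 h with abscisic acid (ABA) or a mock solution; another label gives their age as 10 days after germination, and the sources used here do not settle the difference. RNA was purified on silica columns with DNase digestion, libraries were made with a stranded mRNA kit, and reads came from a NextSeq 500, per the labels' protocols. Per the submitters' processing notes, which give no order or role, the tools included Trimmomatic 0.38, Salmon 1.3.0 and edgeR 3.28.0, with the TAIR10 build. The 2 groups Col-0 mock and Col-0 10 nM ABA hold 2 samples each and the other 8 groups hold 3 each. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicate pairs differed by more than sampling noise in every group, with chi-square values per degree of freedom between 5.353 and 991.5, and no sample was counted as a copy of another.

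The authors deposited a single table of gene-level signal, with 23686 rows and 1 column per sample. The deposited signal was a read count divided by 1 size factor per sample: in every column, 100% of the values were whole multiples of the column's smallest step, within a tolerance of 0.01 read. The steps equalled the reciprocals of size factors recomputed by the median-of-ratios method of DESeq2, with a largest departure of 0%. Dividing by the steps returned between 11.99 and 30.94 M reads per sample. No row held fewer than 10 reads over the 28 samples. Of the rows, 23681 carried a locus identifier and 5 did not, these being MCCA-NOS, PYL4-CA, PYL5-CA, PYL6-CA and PYR1-CA; the 5 were described by their values and kept out of all tests. Positions were taken from the NCBI RefSeq annotation of assembly TAIR10.1, in which 23457 of the loci were found.

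The planned test was a count model in edgeR. Because the values were normalised counts and not raw counts, the main test became limma 3.58.1 on log2(value + 1), with an intensity trend and robust variance shrinkage, in R 4.3.3. Genes entered the test if their value was at least 10 in at least 2 samples, which left 21023 loci. All 28 samples entered a single fit with 1 mean per group, so that the groups of 2 borrowed the spread of the others. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and every adjusted p printed for a gene is from limma unless another tool is named. Log2 differences and folds are on the log2(value + 1) scale, which understates the change of genes with few reads. Means ± SD are of the deposited normalised read counts, and an SE belongs to the fitted log2 difference. The comparisons were aba2-1 mock against Col-0 mock, each ABA dose against mock and against the other dose within each genotype, the genotype by dose interactions, each CA line against Col-0 mock, and an F test among the CA lines.

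The groups, the comparisons, 16 gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The lists held 205 genes chosen from general knowledge: ABA-induced markers, clade A PP2C phosphatases, PYR/PYL receptors, SnRK2 kinases with ABA bZIP/ABI factors, ABA biosynthesis, ABA catabolism and transport, guard cell and stomatal lineage markers, aquaporins, photosynthesis nuclear genes, root tissue markers, seed and embryo markers, jasmonate and wounding markers, salicylate markers, hypoxia markers, cell cycle markers and the circadian clock. Of these genes, 6 were not among the analysed rows (PYL10, PYL13, ABI4, NCED6, CRB and SESA3) and 16 were removed by the filter. Each list was tested with camera of limma, two-sided, against all other genes with a preset inter-gene correlation of 0.01, adjusted over the 208 pairs of list and comparison. A second pass estimated the correlation from the data. Calls of list members were also adjusted over the list alone.

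Named genes were the 4 receptor genes and ABA2 in every group. In the 7 main comparisons they also included the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM and replicates that did not overlap, and up to 4 members per list with the smallest p. In the other comparisons the 5 genes with the smallest p were taken, and in the F test the 10 with the smallest p, again among genes with a mean of at least 5 CPM. The largest rises and falls given in the text are those among genes that met these conditions. Genes outside this rule were named after their values were seen, and the text says where.

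The design was tested on simulated reads with a single real mean and spread per gene, with 50 genes changed by each fold. At 4-fold, the share recovered was 84% for aba2-1 against Col-0 mock, 72% for 10 nM and 84% for 50 nM ABA in Col-0, 94% and 96% for 10 and 50 nM in aba2-1, and 86%, 86%, 90% and 88% for the lines labelled PYR1, PYL4, PYL5 and PYL6 CA. At 2-fold, in the same order, it was 14%, 4%, 10%, 22%, 14%, 10%, 14%, 8% and 14%, so most changes were not recovered. The simulation changed few genes and ignored the wider spread in aba2-1 50 nM ABA and PYL5 CA. In aba2-1 at 50 nM ABA most called genes changed less than 2-fold.

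Depth was uneven. Ribosomal RNA, in 12 rows, took 76.1% of the reads in aba2-1 10 nM ABA replicate 3, which left 3.77 M nuclear reads there. Elsewhere it took 1.5% to 10.5%, and nuclear reads numbered 11.4 to 27.93 M. The settings tried were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, no filter, a stricter filter, fits on only the groups compared, the replicate number as a block, each library left out in turn, and aba2-1 mock as the reference for the CA lines. That edgeR fit used RLE size factors. The edgeR test with TMM, planned as the main test, was run on the recovered reads as well. Added after the data were seen were a pseudocount of 5, TMM rescaling, a spread weighted by group, and a fit without 3 libraries that stood apart (aba2-1 10 nM ABA replicate 3, aba2-1 50 nM ABA replicate 2 and PYL5 CA replicate 3). List and set tests of the CA lines against aba2-1 mock were also added then. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.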

Results

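Transcript levels were measured by RNA sequencing in whole Arabidopsis thaliana seedlings. The samples came from the wild-type accession Col-0, from aba2-1, a mutant of the abscisic acid (ABA) biosynthesis gene ABA2, and from 4 lines labelled PYL4 CA, PYL5 CA, PYL6 CA and PYR1 CA. PYR1 and the PYL proteins are ABA receptors, and CA stands in the receptor literature for constitutively active forms, which signal without the hormone. The labels do not state the genetic background of the CA lines. Col-0 and aba2-1 seedlings were given a mock solution, 10 nM ABA or 50 nM ABA for 3 h, and the CA lines were given the mock solution. Groups held 3 samples each, except Col-0 mock and Col-0 10 nM ABA with 2 each. Totals ranged from 11.99 to 30.94 M reads per sample. Replicates lay far apart in some groups: the median SD of a gene between replicates, on the log2 scale, was 0.326 in aba2-1 50 nM ABA and 0.298 in PYL5 CA, against 0.084 to 0.167 in the other 8 groups. In aba2-1 10 nM ABA replicate 3, ribosomal RNA took 76.1% of the reads.

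**Figure D1:**
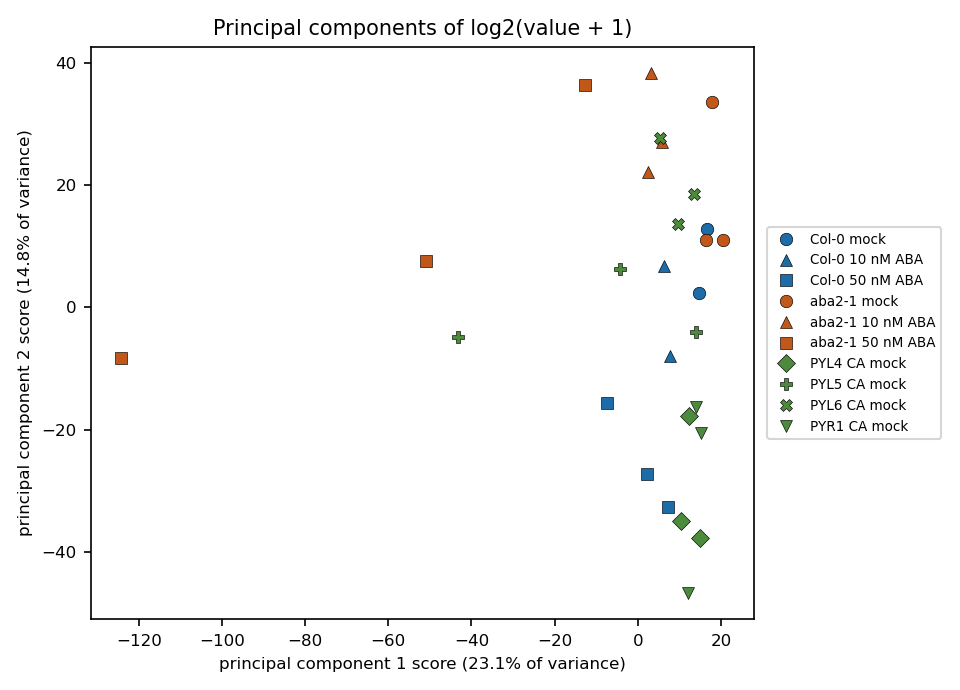
Scores of the 28 libraries on the first and second principal components of log2(value + 1), which held 23.1% and 14.8% of the variance; each point is a library and each marker a group. On the first component the aba2-1 50 nM ABA libraries lie at -50.9, -124.2 and -12.6 and PYL5 CA replicate 3 at -43.2, while all other libraries lie between -7.4 and 20.6.

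The receptor genes and ABA2 were examined first in every group. PYL4 (AT2G38310, chromosome 2, 16049918 to 16051356 in TAIR10.1), PYL5 (AT5G05440, chromosome 5, 1608988 to 1610527), PYL6 (AT2G40330, chromosome 2, 16844588 to 16846194) and PYR1 (AT4G17870, chromosome 4, 9928587 to 9929875) each had a companion row with the suffix CA. The row PYL4-CA held 6197 ± 1650 normalised reads (SD, n = 3) in PYL4 CA and was listed at 0 in both Col-0 mock libraries. PYL5-CA held 10140 ± 2000 in PYL5 CA against 544.5 ± 114 in Col-0 mock, and PYL6-CA held 5450 ± 537 in PYL6 CA against 253.4 ± 51 (n = 3 and 2). PYR1-CA went the other way: it held 450.5 ± 117 in the line labelled PYR1 CA, 591.2 ± 120 in Col-0 mock, 1009 ± 247 in aba2-1 mock and 1729 ± 504 in PYL5 CA. In Col-0 and aba2-1 the rows of PYL5, PYL6 and PYR1 also held reads, with group means from 28.89 to 1104, while PYL4-CA means lay between 0 and 9.082. How reads were divided between a row and its locus was not tested, and each row alone is uncertain. The sum of a locus and its CA row rose from 4601 ± 33.7 in Col-0 mock to 11210 ± 1180 in PYL4 CA for PYL4, from 3272 ± 182 to 15340 ± 3910 in PYL5 CA for PYL5, and from 786.8 ± 122 to 8174 ± 291 in PYL6 CA for PYL6, with no overlap of libraries. The PYR1 sum was 1022 ± 270 in the line labelled PYR1 CA and 3172 ± 356 in Col-0 mock, so the PYR1 reads did not follow that label, and the line is called by its label throughout. The unlocated row MCCA-NOS held 12320 ± 3280, 13710 ± 5320, 22100 ± 4140 and 15950 ± 3140 in the lines labelled PYL4, PYL5, PYL6 and PYR1 CA, and was listed at 0 in Col-0 at all doses and in aba2-1 mock. ABA2 (AT1G52340, chromosome 1, 19489794 to 19491650) held 203.1 ± 24.9 in Col-0 mock and 199.6 ± 11.9 in aba2-1 mock, which checks nothing about the mutation.

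**Figure D2:**
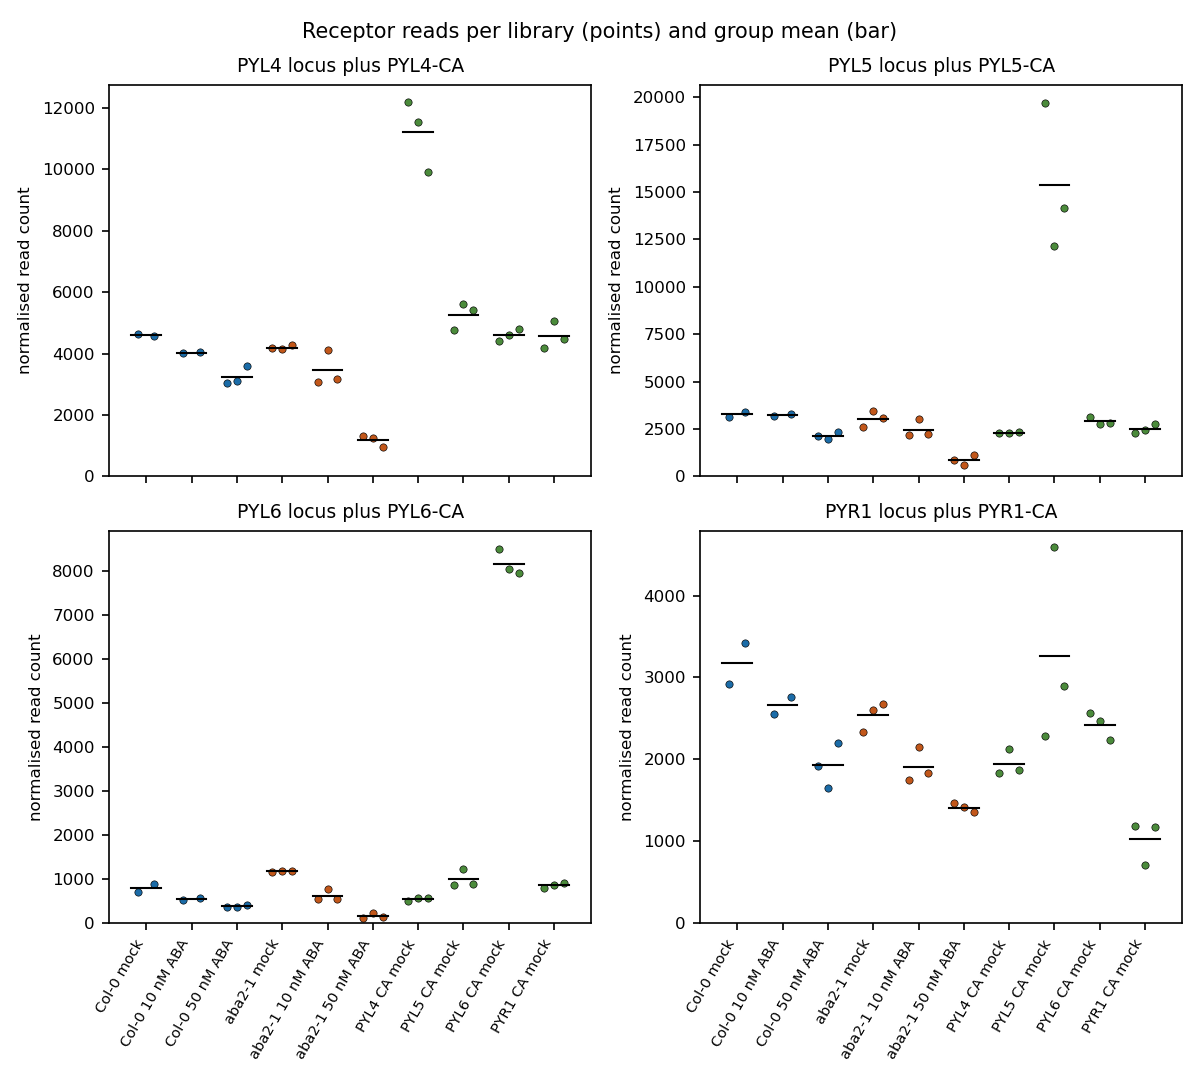
Normalised read counts of each receptor locus plus its CA row (vertical axis, from 0) in the 10 groups (horizontal axis); points are libraries and bars group means. PYL4, PYL5 and PYL6 are highest in the line of the same name, with means of 11210, 15340 and 8174, whereas PYR1 is lowest in the line labelled PYR1 CA, with 1022.

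The first comparison asked how the ABA-deficient mutant differed from wild type in mock. In aba2-1 mock, KIN1, a cold- and ABA-inducible gene, held 107 ± 7.53 normalised reads against 575.5 ± 112 in Col-0 mock (SD, n = 3 and 2), a log2 difference of -2.40 (SE 0.27, adjusted p = 2.2e-05). VSP2, a vegetative storage protein of the jasmonate response, held 24.2 ± 9.76 against 153.5 ± 39.8 (log2 -2.66, adjusted p = 0.00019). The cytochrome P450 gene CYP71A19 held 67.3 ± 7.12 against 379.2 ± 21.2 (log2 -2.48, adjusted p = 4.5e-06), and AT2G05510 and AT3G53980 fell by 2.47 and 2.66. The largest rises were in MRD1, at 828.3 ± 31.6 against 16.64 ± 7.14 (log2 5.62, SE 1.07, adjusted p = 0.015), and HEI10, a meiotic crossover gene, at 368.3 ± 57 against 38.55 ± 12.2 (log2 3.25, adjusted p = 3.7e-05). GSTU11, UGT76E12 and AT5G16980 rose by 2.25, 2.18 and 1.95. MRD1 (chromosome 1, 19963047 to 19964712) and HEI10 (19963267 to 19966952) overlap, so their counts are uncertain, and they start 473.3 and 473.5 kb from ABA2. In Col-0 given ABA, MRD1 ranged from 6.576 to 380.2 between libraries, and whether the Col-0 seed was of a single stock was not tested. The MRD1 call was lost without Col-0 mock replicate 1 (adjusted p = 0.32), Col-0 mock replicate 2 or aba2-1 mock replicate 2, and that of AT3G53980 without Col-0 mock replicate 1 (adjusted p = 0.064). In all, 124 of 21023 genes were called, 65 higher and 59 lower.

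Among the fixed lists, ABA-induced markers were lower as a group in aba2-1 mock (29 measured, median log2 -0.29, adjusted p = 0.0024; adjusted p = 0.23 with an estimated correlation). In that list 1 member rose (MYB102), 2 fell (KIN1 and the lipid transfer gene LTP3) and 26 did not pass; adjusted over the list alone, 1 rose and 4 fell. Hypoxia markers were lower (median -0.70, adjusted p = 1.1e-06; adjusted p = 0.025 with an estimated correlation), with none of 9 members called over all genes and 4 lower adjusted over the list alone. In the jasmonate and wounding list VSP1 and VSP2 fell over all genes and adjusted over the list alone (list adjusted p = 0.012; adjusted p = 0.18 with an estimated correlation). Root tissue markers were higher (median 0.31, adjusted p = 0.0095; adjusted p = 0.3 with an estimated correlation) with no member called. The aquaporin TIP2;3 fell by 1.75 (adjusted p = 0.0042), the only 1 of 18 aquaporins to pass. Of the 14 named-gene calls, 6 held without any single library: HEI10, CYP71A19, AT2G05510, KIN1, VSP2 and AT5G16980; without Col-0 mock replicate 1 or 2, 8 passed. The count of 124 became 33 and 45 without Col-0 mock replicates 1 and 2 and 63 without aba2-1 mock replicate 2, where 13, 21 and 26 were higher and 20, 24 and 37 lower. It was 259 with DESeq2, 363 in a fit on these groups alone, 334 without the 3 libraries that stood apart and 842 with the spread weighted by group.

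**Figure D3:**
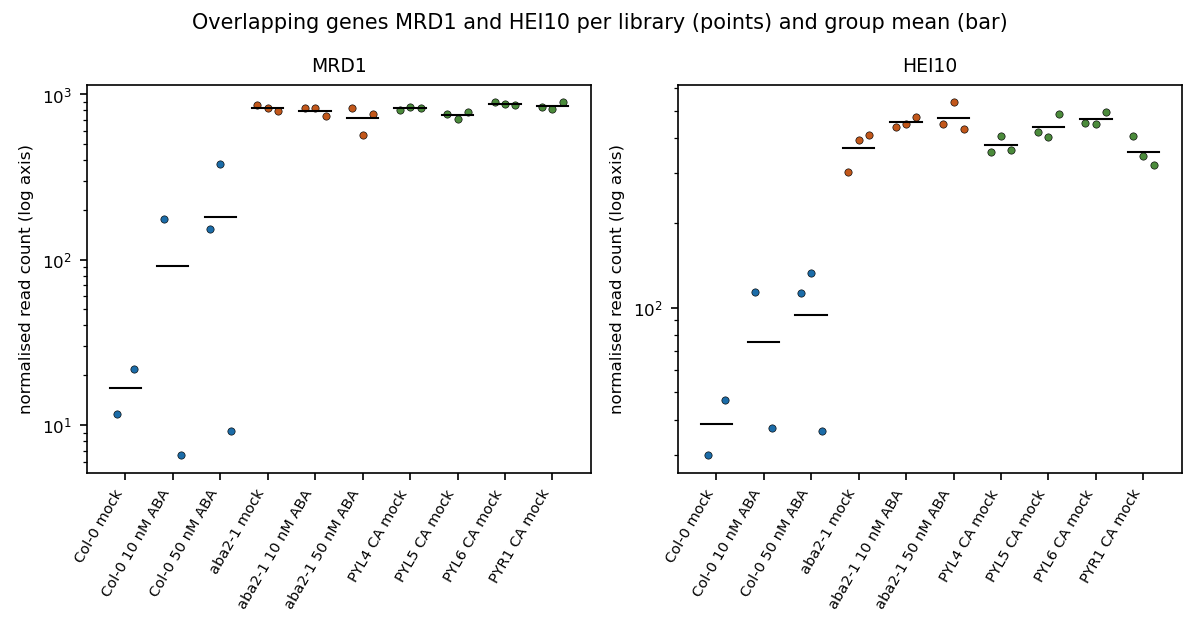
Normalised read counts (log axis) of the overlapping genes MRD1 and HEI10 in the 10 groups; points are libraries and bars group means. In the Col-0 libraries MRD1 ranges from 6.576 to 380.2, and its group means are 720.3 to 828.3 in aba2-1 and 755.4 to 880.6 in the CA lines.

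Col-0 seedlings given 10 nM ABA were compared with mock. The dehydrin gene RAB18 (AT5G66400) held 274.3 ± 35.3 normalised reads against 24.24 ± 11.1 (SD, n = 2 and 2; log2 3.51, SE 0.31, adjusted p = 1.1e-06). PRR9, a clock pseudo-response regulator, held 195.7 ± 22.4 against 65.06 ± 18.7 (log2 1.60, adjusted p = 0.0029), and the expansin gene EXPA16 1072 ± 0.984 against 640.4 ± 52.2 (log2 0.74, adjusted p = 0.017). LEA4-5 at 76.93 ± 10.6 against 17.21 ± 2.99 and AT1G12950 at 52.3 ± 13.5 against 103.5 ± 4.3 did not pass (adjusted p = 0.11 for each). The other calls, RD29B, EM6 and MYB102, list members named after their values were seen, brought the total to 6 higher and 0 lower genes in limma, with 818 genes at an unadjusted p under 0.05. With edgeR 6 were called and with DESeq2 28, of which 19 were higher and 9 lower. ABA-induced markers were higher as a group (median 0.68, adjusted p = 3.1e-30), with 4 of 29 called over all genes and 12 adjusted over the list alone. Clade A PP2C phosphatases (median 0.44, adjusted p = 4.6e-06), SnRK2 kinases with ABA bZIP/ABI factors (median 0.19, adjusted p = 0.00011), the circadian clock (median 0.41, adjusted p = 7.1e-09) and hypoxia markers (median 0.48, adjusted p = 4.5e-07) were also higher. Over all genes only the clock gene PRR9 was called in these; adjusted over the list alone, 3 PP2C, 1 SnRK2 or factor, 5 clock and 2 hypoxia members rose and 1 clock member fell. PYR/PYL receptors were lower (median -0.14, adjusted p = 0.0055) with no member called. Photosynthesis nuclear genes (median -0.17, adjusted p = 0.00037) and cell cycle markers (median -0.22, adjusted p = 0.00026) were lower with the preset correlation only, at an adjusted p of 0.49 and an adjusted p of 0.12 with an estimated correlation. The RAB18 call held without any single library. The count fell to 3 and 1 without Col-0 mock replicates 1 and 2 and to 3 and 1 without Col-0 10 nM ABA replicates 2 and 3. EXPA16, RD29B and EM6 were lost in each of these fits, and MYB102 and PRR9 without Col-0 mock replicate 2 or Col-0 10 nM ABA replicate 3. The count was 441 in a fit on these groups alone and 374 with the spread weighted by group.

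At 50 nM ABA, Col-0 seedlings had 409.6 ± 117 normalised reads of RAB18 (AT5G66400) against 24.24 ± 11.1 in mock (SD, n = 3 and 2; log2 4.06, SE 0.28, adjusted p = 9.2e-09). RD29B, another stress-inducible gene, held 99.64 ± 9.79 against 9.557 ± 1.51 (log2 3.26, adjusted p = 0.00072), and the transcription factor gene MYB102 rose by 5.63 (adjusted p = 2.4e-06). The largest rises chosen by the rule after RAB18 were COR15A (212.7 ± 44.8 against 21.05 ± 5.76, adjusted p = 0.041), GSTU11 (2.94), AT3G23170 (2.66) and LEA4-5 (2.54, 104.4 ± 9.08 against 17.21 ± 2.99). RBCS1B, a Rubisco small subunit gene, held 2624 ± 273 against 6765 ± 978 and fell by 1.36 (adjusted p = 0.025), and AT4G21870, AT4G34810, AT1G12950 and AT1G05250 fell by 1.52, 1.31, 1.15 and 1.08. There were 213 called genes, 166 higher and 47 lower, and 115 and 12 of them changed at least 2-fold. Of the 27 named-gene calls, 7 held without any single library: RAB18, EM6, LBD41, MYB102, PDC1, PRR9 and RD29B. In fits without Col-0 mock replicates 1 and 2, 14 and 8 of the 27 passed, and 16, 19 and 20 without Col-0 50 nM ABA replicates 1, 2 and 3. COR15A and RBCS1B were lost in each of these fits, with adjusted p up to 0.45 and 0.38 without Col-0 mock replicate 2. The count of 213 became 39 and 25 without Col-0 mock replicates 1 and 2 and 60 and 67 without Col-0 50 nM ABA replicates 1 and 2. It was 445 with DESeq2, 929 in a fit on these groups alone, 504 without the 3 libraries that stood apart and 1464 with the spread weighted by group.

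By list, 13 of 29 ABA-induced markers rose at 50 nM ABA in Col-0 and none fell, 17 and 0 adjusted over the list alone (median 1.02, adjusted p = 2e-28). Of the clade A PP2C phosphatases, which bind ABA receptors, ABI2 rose (130.7 normalised reads against 62.98, adjusted p = 0.0086), and 4 rose adjusted over the list alone (list adjusted p = 1.1e-06). In the SnRK2 kinase and factor list ABF1, OST1 and SNRK2.9 rose, with log2 differences of 0.60, 0.58 and 1.28, and 4 rose adjusted over the list alone (list adjusted p = 0.00011). CYP707A1, which encodes an ABA-degrading hydroxylase, held 359.1 ± 39.2 against 150.2 ± 18.3 (log2 1.25, adjusted p = 0.0016), with 3 members of its list higher adjusted over the list alone (list adjusted p = 1.2e-05). Hypoxia markers were higher (median 1.18, adjusted p = 3.4e-11): pyruvate decarboxylase PDC1, LBD41, the cysteine oxidase PCO2 and alcohol dehydrogenase ADH1 rose by 2.09, 2.27, 1.94 and 1.2, and 6 of 9 rose adjusted over the list alone. PRR9, GI and PRR5 rose and LHY fell in the clock list (5 and 2 adjusted over the list alone; list adjusted p = 0.00073, adjusted p = 0.099 with an estimated correlation). The lipoxygenase LOX2 rose by 1.52 (adjusted p = 0.049) in the jasmonate list (2 adjusted over the list alone; list adjusted p = 0.0033, adjusted p = 0.099 with an estimated correlation). PYR/PYL receptors (median -0.18, adjusted p = 0.00075) and guard cell markers (median -0.39, adjusted p = 0.0045) were lower with no member called over all genes and 4 and 1 lower adjusted over the list alone. PYL4, PYL5, PYL6 and PYR1 had log2 differences of -0.51, -0.64, -1.2 and -1.11 that did not pass. Photosynthesis genes were lower (median -0.36, adjusted p = 1.4e-07; adjusted p = 0.28 with an estimated correlation), with RBCS1B called and 3 lower adjusted over the list alone.

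No gene was called by limma between 50 and 10 nM ABA in Col-0 (0 genes, 763 at an unadjusted p under 0.05), nor by edgeR (0), while DESeq2 called 6. Among genes with a mean of at least 5 CPM the smallest p belonged to AOC2, an enzyme of jasmonate synthesis, at 2557 ± 858 normalised reads against 1192 ± 138 (SD, n = 3 and 2; adjusted p = 0.77). AT5G16010 (2048 ± 529 against 885.8 ± 18.8), AT1G22810 (86.37 ± 10.6 against 36.52 ± 7.25), AT4G25620 (1081 ± 52 against 1489 ± 63.8) and AT1G06000 followed without passing. Guard cell and stomatal lineage markers were lower at 50 nM as a group (median -0.28, adjusted p = 0.0017; adjusted p = 0.014 with an estimated correlation). ABA-induced markers were higher (median 0.15, adjusted p = 0.0096; adjusted p = 0.32 with an estimated correlation), as were hypoxia markers (median 0.61, adjusted p = 8.3e-05; adjusted p = 0.07 with an estimated correlation), of which 3 were higher and 1 lower adjusted over the list alone. The count was 10 in a fit on these groups alone and 46 with the spread weighted by group, and 0 without each of the 5 libraries in turn.

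In aba2-1 at 10 nM ABA, RAB18 (AT5G66400) held 245.8 ± 64.4 normalised reads against 16.2 ± 2.41 in aba2-1 mock (SD, n = 3 and 3; log2 3.82, SE 0.25, adjusted p = 3.1e-09). CYP71A19 held 286.2 ± 50.3 against 67.3 ± 7.12 (log2 2.06, adjusted p = 1.8e-05) and the annexin gene ANNAT7 177.4 ± 18.5 against 52.58 ± 5.22 (log2 1.74, adjusted p = 3.3e-05). AT5G60760 held 118.6 ± 17.9 against 338.9 ± 29.9 (log2 -1.51, adjusted p = 3.3e-05), and AT1G11540 fell by 1.61. These 5 calls held without any single library. Among ABA-induced markers 9 of 29 rose and none fell, 19 and 0 adjusted over the list alone (median 0.75, adjusted p = 5.9e-33). Of the PP2C phosphatases 2 rose, and 6 adjusted over the list alone (list adjusted p = 6.2e-07), and 1 SnRK2 kinase or factor rose, and 2 adjusted over the list alone (list adjusted p = 6e-05). In the PYR/PYL list 1 receptor fell, and 2 adjusted over the list alone (median -0.22, adjusted p = 0.0014). Hypoxia markers were higher (median 0.59, adjusted p = 0.0033; adjusted p = 0.18 with an estimated correlation). The call count was 205, with 106 higher and 99 lower; DESeq2 gave 181 and 110. It became 99, 117 and 118 without aba2-1 mock replicates 1, 2 and 3 and 128 without aba2-1 10 nM ABA replicate 2.

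At 50 nM ABA in aba2-1, RAB18 (AT5G66400) reached 1121 ± 337 normalised reads against 16.2 ± 2.41 in mock (SD, n = 3 and 3; log2 6, SE 0.25, adjusted p = 1.6e-13). The late embryogenesis abundant gene LEA4-5 held 464.4 ± 73.2 against 11.89 ± 5.96 (log2 5.27, adjusted p = 7.1e-10) and KIN1 1223 ± 248 against 107 ± 7.53 (log2 3.48, adjusted p = 7.8e-10). COR15A held 402.2 ± 116 against 23.2 ± 19.8 (log2 4.41, adjusted p = 0.00013) and CYP71A19 698.1 ± 256 against 67.3 ± 7.12 (log2 3.30, adjusted p = 7.1e-10). The largest falls were in AT4G34810 (log2 -3.37), AT4G21870 (62.83 ± 21.4 against 639.2 ± 148, log2 -3.36), AT1G05700 (49.61 ± 17.9 against 492.2 ± 31.3, log2 -3.35), AT1G06830 (log2 -3.09) and AT5G61160 (log2 -2.83). Calls numbered 5210, with 2660 higher and 2550 lower, and 754 and 609 of them changed at least 2-fold. The split was 3080 to 2085 with edgeR and 3276 to 2284 with DESeq2. Of the 51 named-gene calls, 42 held without any single library; ABA1, CYCB1;3, ELF3, LHCB3, OPR3, PIP1;5, PIP2;8, TMM and TOC1 did not, and 42 passed without aba2-1 mock replicate 3 or aba2-1 50 nM ABA replicate 2. The count became 3440, 3349 and 3041 without aba2-1 mock replicates 1, 2 and 3, 2086 (993 higher, 1093 lower) without aba2-1 50 nM ABA replicate 2 and 9272 without its replicate 3. It was 543 in a fit on these groups alone, 1410 with the spread weighted by group and 2903 without the 3 libraries that stood apart.

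**Figure D4:**
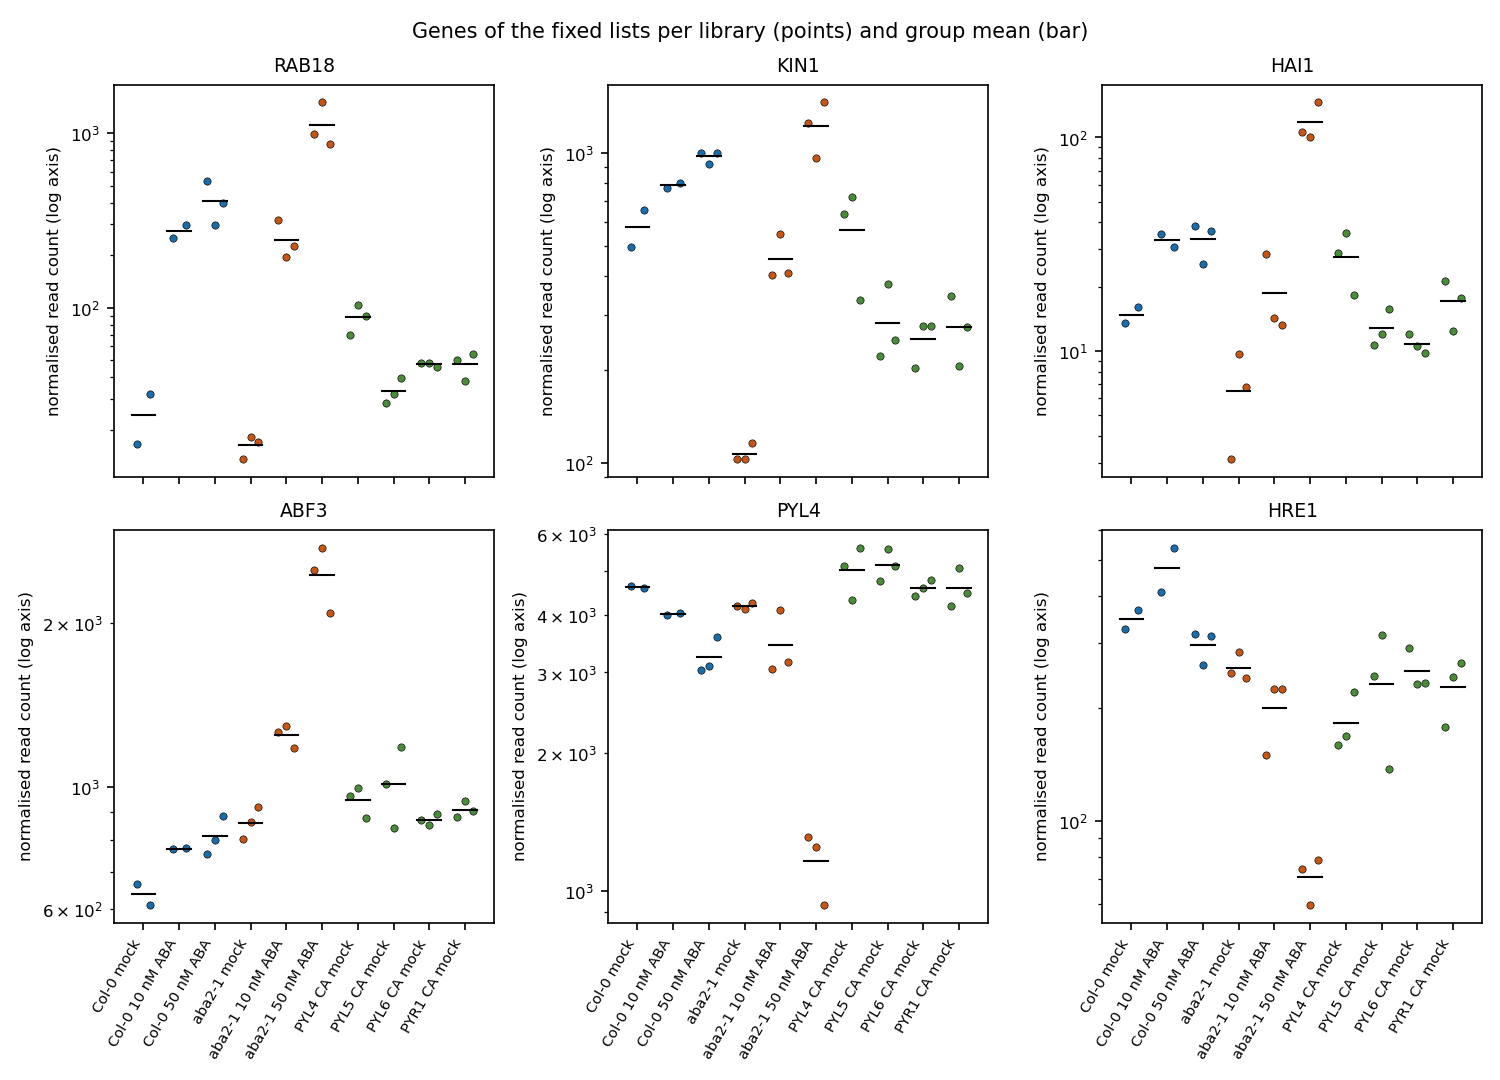
Normalised read counts (log axis) of RAB18, KIN1, HAI1, ABF3, PYL4 and HRE1 in the 10 groups; points are libraries and bars group means. In aba2-1, RAB18 means are 16.2, 245.8 and 1121 at mock, 10 nM and 50 nM ABA, and PYL4 falls from 4188 in mock to 1165 at 50 nM.

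Genes of ABA signalling moved in opposite directions in aba2-1 at 50 nM ABA. Of 29 ABA-induced markers 28 rose over all genes and 29 adjusted over the list alone (median 2.39, adjusted p = 2e-34). Besides RAB18 and KIN1 they included the homeodomain gene ATHB7 (1243 ± 370 against 222.4 ± 36.1) and P5CS1 of proline synthesis (log2 1.25). All 7 clade A PP2C phosphatases rose, over all genes and adjusted over the list alone (median 1.25, adjusted p = 1.5e-09): HAI1 by log2 4.07 to 117.7 ± 24.7, ABI1 from 1317 ± 68.3 to 2633 ± 278, and ABI2 and HAB1 by log2 1.67 and 1.25. The SnRK2 and factor list had 10 members higher (11 higher and 1 lower adjusted over the list alone; median 0.60, adjusted p = 1.2e-06), among them ABF3, a bZIP factor, at 2439 ± 331 against 862.4 ± 57.8 and the kinase OST1 (log2 0.79). In contrast, 4 of the PYR/PYL receptors fell, over all genes and adjusted over the list alone (median -0.34, adjusted p = 0.00047). PYL4 held 1165 ± 202 against 4188 ± 58.7 (log2 -1.86), PYL5 544.5 ± 80.6 against 2462 ± 169 (log2 -2.18), and PYL6 and PYR1 fell by 2.76 and 1.59. The sums with the CA rows were lower as well: from 4197 to 1172 for PYL4, 3037 to 877.9 for PYL5, 1175 to 155.8 for PYL6 and 2538 to 1408 for PYR1.

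In the same comparison, catabolism and transport genes were higher (median 0.32, adjusted p = 0.016; adjusted p = 0.17 with an estimated correlation), with 3 called over all genes and adjusted over the list alone: CYP707A1 (316.2 against 109.1), CYP707A2 and the ABA exporter ABCG25. ABA biosynthesis genes did not pass as a list (median 0.22, adjusted p = 0.067), though NCED3 and ABA1 rose by 1.26 and 0.27 (2 higher adjusted over the list alone). Hypoxia markers were higher (median 1.04, adjusted p = 0.045; adjusted p = 0.37 with an estimated correlation), with 6 members higher and 1 lower, over all genes and adjusted over the list alone. PDC1, ADH1 and the sucrose synthase SUS1 rose by 1.63, 1.23 and 1.15, and the low-oxygen factor HRE1 fell from 257.4 ± 21.9 to 70.71 ± 9.85. The circadian clock was higher (median 0.21, adjusted p = 0.045; adjusted p = 0.35 with an estimated correlation), with PRR9, GI, ELF3 and TOC1 called and 5 adjusted over the list alone. Photosynthesis genes were lower (median -0.51, adjusted p = 0.0045; adjusted p = 0.61 with an estimated correlation): RBCS1B fell from 4659 ± 663 to 1254 ± 522 and LHCB3 by 1.12, and 1 fell adjusted over the list alone. The photosynthesis medians of the libraries deviated from their group mean by 0.03, -0.62 and 0.60 in aba2-1 50 nM ABA replicates 1, 2 and 3, and the aquaporin medians by 0.14, -0.74 and 0.52.

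The other lists did not pass. Guard cell markers had 2 members higher and 2 lower, over all genes and adjusted over the list alone (median 0.20, adjusted p = 0.56). The malate channel gene ALMT12 rose from 74.79 to 194.2 and the anion channel gene SLAC1 by 0.80, while HT1 and TMM fell by 1.04 and 0.62. Aquaporins likewise had 2 higher (TIP2;3, PIP2;6) and 2 lower (PIP1;5, PIP2;8) by either adjustment (median -0.26, adjusted p = 0.45). Root tissue markers had a median of 0.02 but a test direction of lower (adjusted p = 0.7); the nitrate transporter NRT2.1 fell by 3.29 and PHO1 by 0.51, the latter with an adjusted p that rounds to 0.05, and 1 fell adjusted over the list alone. In the jasmonate list VSP2 rose by 1.89 and OPR3 fell by 0.51 (3 higher and 1 lower adjusted over the list alone), with a median of -0.23 against a test direction of higher (adjusted p = 0.74). CYCB1;3 was the 1 of 9 cell cycle markers called, lower by either adjustment (list median -0.17, adjusted p = 0.33). Salicylate markers (median -0.32, adjusted p = 0.46) and seed and embryo markers (median 0.47, adjusted p = 0.62) had no member called.

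Between 50 and 10 nM ABA in aba2-1, ATHB7 held 1243 ± 370 normalised reads against 288.3 ± 47.2 (SD, n = 3 and 3; log2 2.08, adjusted p = 3.2e-07) and AT1G16850 378.2 ± 112 against 87.11 ± 5.98 (log2 2.06, adjusted p = 8.3e-07). PYL4 held 1165 ± 202 against 3442 ± 572 (log2 -1.56, adjusted p = 2e-07), AT2G43140 210.9 ± 47 against 837.5 ± 155 (log2 -1.99, adjusted p = 4.1e-09), and AT4G21870 fell by 2.55. These 5 calls held without any single library. ABA-induced markers were higher at 50 nM (23 of 29, 27 adjusted over the list alone; median 1.42, adjusted p = 7.1e-25), as were PP2C phosphatases (6, and 7 adjusted over the list alone; adjusted p = 6.3e-08). PYR/PYL receptors were lower (4, and 4 adjusted over the list alone; adjusted p = 0.0025). There were 2430 calls, 1279 higher and 1151 lower, and edgeR and DESeq2 split theirs 1485 to 765 and 2000 to 1120. Leaving out aba2-1 10 nM ABA replicates 1, 2 and 3 gave 1114, 939 and 1178, and leaving out aba2-1 50 nM ABA replicates 1, 2 and 3 gave 1566, 485 (219 higher, 266 lower) and 8230. The count was 6 in a fit on these groups alone, 75 with the spread weighted by group and 565 without the 3 libraries that stood apart.

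Whether the genotypes differed in response was tested by the interaction of genotype and dose. At 10 nM, limma called 0 genes (654 at an unadjusted p under 0.05), edgeR 0 and DESeq2 3. AT5G60760 had the smallest p: it held 102.6 ± 0.264 normalised reads in mock and 100.3 ± 11.6 at 10 nM in Col-0 but 338.9 ± 29.9 and 118.6 ± 17.9 in aba2-1 (n = 2, 2, 3 and 3; log2 interaction -1.48, SE 0.27, adjusted p = 0.33). CYP71A19 (1.66), PLA2A (-1.94), UGT76E12 (-2.17) and AT2G36770 (-2.07) did not pass either. AT5G60760 passed with DESeq2 (adjusted p = 0.0053). At 50 nM, 431 genes were called, 128 with a more positive and 303 with a more negative response in aba2-1; DESeq2 gave 430 and 544. CYP71A19 went from 379.2 to 529.4 in Col-0 and from 67.3 to 698.1 in aba2-1 (log2 interaction 2.83, SE 0.33, adjusted p = 9e-05). ABCG14, a cytokinin transporter gene, went from 811.8 to 920.1 and from 1297 to 454.1 (log2 interaction -1.68, SE 0.19), AT1G05700 from 291.8 to 184.1 and from 492.2 to 49.61 (-2.67), AT3G50010 from 158.6 to 144.7 and from 199.2 to 41.46 (-2.11), and MDHAR from 721.6 to 627.7 and from 1162 to 343.6 (-1.57). ABA-induced markers responded more in aba2-1 (14 of 29 called, 17 higher and 1 lower adjusted over the list alone; median interaction 1.39, adjusted p = 8.9e-18), as did PP2C phosphatases with ABI1 and HAI1, named after their values were seen, called (6 adjusted over the list alone, adjusted p = 2.2e-06). The ABI1 call was lost in a fit on these groups alone (adjusted p = 0.082). The PYL4 and PYL5 responses were more negative (PYR/PYL list adjusted p = 0.0086; 3 adjusted over the list alone). The 5 named calls held without any single library. The count became 143 and 139 without Col-0 mock replicates 1 and 2, 216 and 279 without Col-0 50 nM ABA replicates 1 and 2, 267 without aba2-1 mock replicate 3 and 3338 without aba2-1 50 nM ABA replicate 3, where 1802 were more positive and 1536 more negative. It was 130 in a fit on these groups alone and 193 with the spread weighted by group.

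Each CA line was then compared with Col-0 mock, which cannot separate receptor from background. In the line labelled PYR1 CA, PYR1 itself held 571.2 ± 163 normalised reads against 2581 ± 236 (SD, n = 3 and 2; log2 -2.22, SE 0.30, adjusted p = 0.00027). AT3G53980, AT2G16005, CYP71A19 and AT2G05510 fell by 2.87, 2.45, 2.33 and 2.27. AT2G16005 held 88.74 ± 6.81 against 488.1 ± 46.2 (adjusted p = 1.1e-05). The largest rises were in MRD1 (851.3 ± 39.3 against 16.64 ± 7.14, adjusted p = 0.0069), HEI10 (357.3 ± 44.7 against 38.55 ± 12.2, adjusted p = 6.1e-05), GSTU11 (log2 2.76), AT1G05675 (2.34) and the ABA importer gene ABCG40 (1412 ± 591 against 197.3 ± 21.6, adjusted p = 0.0032). Calls numbered 591, with 443 higher and 148 lower. The 9 of 27 named-gene calls that held without any single library were AT2G05510, AT2G16005, AT3G53980, CRU3, CYP71A19, HEI10, MYB102, PYR1 and TIP2;3. MRD1 and GSTU11 were lost without either Col-0 mock replicate (adjusted p up to 0.11 and 0.077, without replicate 1) and ABCG40 without Col-0 mock replicate 2 (adjusted p = 0.078). Against aba2-1 mock, the only reference planned besides Col-0 mock, 242 genes were called, 218 higher and 24 lower, and HEI10 (-0.04), CYP71A19 (0.15), AT2G05510 (0.19), LTP3 (0.18), VSP2 (0.47) and KIN1 (1.32) changed sign. The count against Col-0 mock became 102 and 42 without Col-0 mock replicates 1 and 2 and 148 without PYR1 CA replicate 2. It was 1082 with DESeq2, 1561 in a fit on these groups alone, 1363 without the 3 libraries that stood apart and 3693 with the spread weighted by group.

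By list, the line labelled PYR1 CA had 6 ABA-induced markers higher and 2 lower (8 and 3 adjusted over the list alone; median 0.31, adjusted p = 0.0085, adjusted p = 0.31 with an estimated correlation). MYB102, EM6 and MYB74 rose and LTP3 fell. KIN1, named after its values were seen, also fell (log2 -1.08, adjusted p = 0.028), but the call was lost without either Col-0 mock replicate or PYR1 CA replicate 2 or 3 (adjusted p up to 0.42), and against aba2-1 mock it rose by 1.32 (adjusted p = 0.0088). CYP707A1 (309.2 ± 14.6 against 150.2 ± 18.3) and ABCG40 rose in the catabolism and transport list (4 adjusted over the list alone; list adjusted p = 0.0051, adjusted p = 0.1 with an estimated correlation). ABI2 rose by 0.81 and ABF3 by 0.51. Seed and embryo markers were higher (adjusted p = 4.6e-05): the cruciferin genes CRU3 and CRA1 held 32.16 ± 34.3 and 180 ± 246, against listed values of 0 and 0 for CRU3 and 1.932 ± 2.73 for CRA1 in Col-0 mock, and 3 members were higher adjusted over the list alone. Salicylate markers were higher (adjusted p = 0.0044; adjusted p = 0.11 with an estimated correlation), with the glucanase gene PR2 called at 55.93 ± 34.4 against 3.347 and 3 adjusted over the list alone. VSP2 and VSP1 fell by 2.18 and 1.87 while AOS, a jasmonate synthesis gene, rose by 1.06, and the jasmonate list did not pass (median 0.33, adjusted p = 0.73). TIP2;3 and TIP2;2 fell by 2.15 and 1.19 in the aquaporin list (2 adjusted over the list alone; adjusted p = 0.044, adjusted p = 0.72 with an estimated correlation), SUS4 by 1.19 among hypoxia markers (adjusted p = 0.0069, adjusted p = 0.22 with an estimated correlation) and CYCB1;4 by 0.46 among cell cycle markers (adjusted p = 0.00044, adjusted p = 0.14 with an estimated correlation). Without Col-0 mock replicates 1 and 2, 12 and 11 of the 27 named-gene calls passed, and 16 without PYR1 CA replicate 2. CRA1 was lost without Col-0 mock replicate 2 (adjusted p = 0.28) and PR2 without either Col-0 mock replicate or PYR1 CA replicate 1 or 2 (adjusted p up to 0.33).

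In PYL4 CA, RAB18 (AT5G66400) held 87.83 ± 16.9 normalised reads against 24.24 ± 11.1 in Col-0 mock (SD, n = 3 and 2; log2 1.87, adjusted p = 0.0017) and RD29B 67.46 ± 12.6 against 9.557 ± 1.51 (log2 2.69, adjusted p = 0.0059). By size the leading rises were MRD1 (824.9 ± 16.7 against 16.64 ± 7.14, adjusted p = 0.013), HEI10 (376.3 ± 27.4 against 38.55 ± 12.2, log2 3.29, adjusted p = 0.00012), AT1G26380 (444.2 ± 249 against 48.25 ± 5.55, adjusted p = 0.0067), BCS1 (log2 2.74) and AT1G05675 (log2 2.59). AT1G19650, AT4G21445, AT5G43520, AT4G21870 and AT3G60290 fell by 1.29, 1.27, 1.25, 1.25 and 1.16. Of 29 ABA-induced markers 4 rose, with MYB102 and EM6 beside RAB18 and RD29B, and 9 were higher and 1 lower adjusted over the list alone (median 0.29, adjusted p = 1.1e-05; adjusted p = 0.083 with an estimated correlation). Catabolism and transport genes were higher (median 0.59, adjusted p = 6.1e-05), with CYP707A1 (307 ± 80.2 against 150.2 ± 18.3) and ABCG40 (890.2 ± 288 against 197.3 ± 21.6) called and 5 adjusted over the list alone. PP2C phosphatases were higher (median 0.39, adjusted p = 0.0017), with ABI2 called over all genes and adjusted over the list alone. ABF3, AAO3 of ABA synthesis, the root hair factor RSL4, LBD41 and PRR9 rose by 0.57, 0.72, 1.26, 1.68 and 0.87, and the root tissue list was higher (adjusted p = 0.01; adjusted p = 0.3 with an estimated correlation). There were 302 calls, 256 higher and 46 lower. Of the 22 named-gene calls, HEI10 alone held without any single library, and 2, 3 and 8 passed without Col-0 mock replicates 1 and 2 and PYL4 CA replicate 1. RAB18 was lost only without Col-0 mock replicate 1 (adjusted p = 0.08) and RD29B without either Col-0 mock replicate (adjusted p up to 0.16). The count became 10 and 11 without Col-0 mock replicates 1 and 2 and 32 and 145 without PYL4 CA replicates 1 and 3. It was 700 with DESeq2, 1857 in a fit on these groups alone, 847 without the 3 libraries that stood apart and 2882 with the spread weighted by group. Against aba2-1 mock it was 522, 415 higher and 107 lower, with VSP2 (2.12) of opposite sign and MRD1 at -0.01.

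In PYL5 CA, MRD1 (755.4 ± 37.9 normalised reads against 16.64 ± 7.14 in Col-0 mock; SD, n = 3 and 2; adjusted p = 0.011) and HEI10 (436.5 ± 45 against 38.55 ± 12.2, log2 3.5, adjusted p = 3.4e-05) again led the rises, before GSTU11 (log2 2.84), AT5G16980 (2.03) and UGT76E12 (1.97). VSP2 held 31 ± 17.5 against 153.5 ± 39.8 (log2 -2.38, adjusted p = 0.00077) and VSP1 89.47 ± 43.9 against 354.1 ± 59.4 (log2 -2.07, adjusted p = 0.001), and AT3G53980, AT2G16005 and CYP71A19 fell by 2.63, 2.24 and 2.14. The PYL5 locus held 5206 ± 2000 against 2727 ± 67.9 (adjusted p = 0.026). Among ABA-induced markers MYB102, MYB74 and AFP1 rose and LTP3 and KIN1 were the 2 called lower (7 higher and 3 lower adjusted over the list alone; median 0.37, adjusted p = 0.004, adjusted p = 0.27 with an estimated correlation). SnRK2 kinases and factors were higher (median 0.24, adjusted p = 0.00097), with ABF3 called and 2 adjusted over the list alone. Hypoxia markers were lower (median -0.65, adjusted p = 0.00015; adjusted p = 0.083 with an estimated correlation), with SUS4 called and 4 adjusted over the list alone, and the aquaporin TIP2;3 fell by 1.5. In PYL5 CA replicates 1, 2 and 3 the photosynthesis medians deviated from the group mean by -0.07, 0.62 and -0.54. The count was 334, 213 higher and 121 lower. Of 18 named-gene calls, AT2G16005, AT5G16980, CYP71A19, HEI10 and LTP3, 5 in all, held without any single library, and 7 and 8 passed without Col-0 mock replicates 1 and 2. VSP2 and VSP1 were lost only without Col-0 mock replicate 1 (adjusted p = 0.055 and 0.059), and the PYL5 locus without either Col-0 mock replicate or PYL5 CA replicate 1 or 3 (adjusted p up to 0.26). KIN1, named after its values were seen (log2 -1.05, adjusted p = 0.046), was lost without the same 4 libraries (adjusted p up to 0.41). Omitting Col-0 mock replicates 1 and 2 gave 29 and 49 calls and omitting PYL5 CA replicate 2 gave 1137, with 509 higher and 628 lower, so the majority turned. The count was 781 with DESeq2, 13 in a fit on these groups alone, 88 with the spread weighted by group and 732 without the 3 libraries that stood apart. Against aba2-1 mock 33 genes were called, 20 higher and 13 lower, and MRD1 (-0.13), UGT76E12 (-0.21), AT3G53980 (0.03), VSP2 (0.28), AT2G16005 (0.12), CYP71A19 (0.34), TIP2;3 (0.25) and KIN1 (1.36, adjusted p = 0.018) changed sign.

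PYL6 CA differed from Col-0 mock at 33 genes, 15 higher and 18 lower. The PYL6 locus held 2724 ± 416 normalised reads against 533.4 ± 71.2 (SD, n = 3 and 2; log2 2.35, adjusted p = 0.00098). TBL23, a cell wall acetylation family gene, held 674.4 ± 111 against 213 ± 22.6 (log2 1.65, adjusted p = 5.3e-06) and the zinc transporter gene ZIP3 201.8 ± 24 against 81.75 ± 16.9 (log2 1.3, adjusted p = 0.0022), beside MRD1 (880.6 ± 16.6 against 16.64 ± 7.14) and HEI10 (465.6 ± 25.7 against 38.55 ± 12.2). AT3G59930 held 53.82 ± 3.84 against 173.6 ± 7.82 (log2 -1.67, adjusted p = 0.00021), and AT2G05510, AT2G16005, EXPB3 and CYP71A19 fell by 1.36, 1.32, 1.27 and 1.27. ABA-induced markers did not pass as a list (median 0.11, adjusted p = 0.49), with LTP3 lower and, adjusted over the list alone, 2 higher and 2 lower. SnRK2 kinases and factors (median 0.17, adjusted p = 0.001) and PP2C phosphatases (median 0.21, adjusted p = 0.0096; adjusted p = 0.098 with an estimated correlation) were higher with no member called over all genes and 1 each adjusted over the list alone. Cell cycle markers were lower (median -0.26, adjusted p = 8.3e-05; adjusted p = 0.098 with an estimated correlation) with no member called. The calls of HEI10, TBL23 and AT3G59930, 3 of 11 named, held without any single library. The PYL6 locus was lost only without Col-0 mock replicate 1 (adjusted p = 0.053) and ZIP3 only without Col-0 mock replicate 2 (adjusted p = 0.19). MRD1 was lost without any 1 of the 5 libraries (adjusted p up to 0.57). The count became 12 and 13 without Col-0 mock replicates 1 and 2 and 15 and 20 without PYL6 CA replicates 1 and 3. It was 108 with DESeq2, 512 in a fit on these groups alone, 103 without the 3 libraries that stood apart and 1489 with the spread weighted by group. Against aba2-1 mock, where 15 genes were higher and 10 lower, AT2G05510 (1.11), AT2G16005 (1.04), CYP71A19 (1.21), KIN1 (1.21) and VSP2 (1.53) changed sign.

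Differences among the 4 CA lines were tested without reference to Col-0. TBL23 held 674.4 ± 111 normalised reads in PYL6 CA against 217.2 ± 37.9 in PYL5 CA, 237.7 ± 8.54 in PYL4 CA and 244.7 ± 11.3 in the line labelled PYR1 CA (SD, n = 3 each; F test, adjusted p = 1.2e-06). IGMT5, a methyltransferase gene of indole glucosinolate synthesis, held 1616 ± 105 in PYL4 CA, 853.3 ± 79.1 in the line labelled PYR1 CA, 726.9 ± 87.1 in PYL6 CA and 681.2 ± 41.4 in PYL5 CA (adjusted p = 1.2e-06). The transporter gene ABCC3 held 6732 ± 2400 and 5511 ± 1640 in PYL4 CA and the line labelled PYR1 CA, and 2102 ± 341 and 1982 ± 129 in PYL5 CA and PYL6 CA (adjusted p = 3e-05). AT2G16005 was lowest in the line labelled PYR1 CA and PYL5 CA, at 88.74 and 102.6, against 197 in PYL6 CA and 323.5 in PYL4 CA. AT2G05510 followed the same order. AT3G59930, AT1G33811, AT5G60760, MLP329 and AT4G11190 completed the 10 smallest p among genes with a mean of at least 5 CPM, with adjusted p between 1.9e-05 and 2e-04. In all, 706 genes were called, 1790 with DESeq2, 1222 without the 3 libraries that stood apart and 2582 with the spread weighted by group. The 10 named calls held without any single library, but the count became 335 and 441 without PYL4 CA replicates 1 and 3, 1146 without PYL5 CA replicate 1, 412 and 296 without PYL6 CA replicates 1 and 3, and 460 without PYR1 CA replicate 2.

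Genes called in aba2-1 at 50 nM ABA were then followed as sets in comparisons sharing no library with the call. The 2660 genes higher in aba2-1 were higher in Col-0 at 50 nM ABA (median log2 0.10, adjusted p = 4.1e-10), and 86 were called there against 21 for independent lists. The 2550 lower genes were lower (median -0.12, adjusted p = 3e-10), with 35 called against 5.7. In PYL5 CA the medians were 0.27 (adjusted p = 3.2e-18) and -0.23 (adjusted p = 6.6e-11). Of the higher set 84 were called higher there, against 27 for independent lists, but 30 were called lower, against 15.3. Of the lower set 43 were called lower, against 14.7, and 19 higher, against 25.8. PYL5 CA replicate 3 and aba2-1 50 nM ABA replicate 2 deviated together from their group means (r = 0.52 across genes, which are not independent replicates). In PYL6 CA the medians were 0.08 (adjusted p = 0.0048) and -0.07 (adjusted p = 0.0075), but called members did not follow: 2 of the higher set were called higher and 6 lower, and 3 of the lower set lower and 5 higher. In PYL4 CA (medians 0.03 and -0.04) and in the line labelled PYR1 CA (0.01 and 0.01) the sets did not pass. With an estimated correlation none of the 10 set tests passed (adjusted p of 0.61 for both sets in Col-0 at 50 nM and in PYL5 CA, and adjusted p of 0.9 for both in PYL6 CA).

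Other sets were added after the data were seen, because without aba2-1 50 nM ABA replicate 2 the 5210 calls fell to 2086. Without any single library, 818 of the higher and 864 of the lower genes stayed called. In Col-0 at 50 nM ABA these had medians of 0.26 (adjusted p = 3.7e-28; adjusted p = 0.031 with an estimated correlation) and -0.17 (adjusted p = 2e-16; adjusted p = 0.042 with an estimated correlation). The 818 genes were higher in PYL4 CA (median 0.13, adjusted p = 3.8e-07; adjusted p = 0.34 with an estimated correlation), with 34 called against 9.96 for independent lists. They were also higher in PYL5 CA (median 0.29, adjusted p = 5.5e-13; adjusted p = 0.16 with an estimated correlation) and PYL6 CA (median 0.11, adjusted p = 0.0016; adjusted p = 0.53 with an estimated correlation), and did not pass in the line labelled PYR1 CA (median 0.07, adjusted p = 0.11). In PYL5 CA 48 of them were called higher, against 8.29 for independent lists, and 28 lower, against 4.71. In PYL6 CA called members went the other way, with 0 higher and 6 lower, against 0.584 and 0.7. In the line labelled PYR1 CA 40 were called higher, against 17.2, and 32 lower, against 5.76. The 864 genes were lower in PYL5 CA (median -0.12, adjusted p = 0.0026; adjusted p = 0.48 with an estimated correlation), with 26 called lower against 4.97 and 13 higher against 8.75. In the line labelled PYR1 CA they were higher, against the direction in aba2-1 (median 0.12, adjusted p = 0.001; adjusted p = 0.48 with an estimated correlation). They did not pass in PYL4 CA (median -0.01, adjusted p = 0.67) or PYL6 CA (median -0.02, adjusted p = 0.36). The sets called in aba2-1 at 10 nM ABA did not pass in PYL5 CA (adjusted p of 0.66 for the higher and 0.19 for the lower set). In PYL6 CA the higher of them had a median of 0 and a test direction of lower (adjusted p = 0.03; adjusted p = 0.34 with an estimated correlation), and the lower was higher (median 0.18, adjusted p = 0.00056; adjusted p = 0.23 with an estimated correlation).

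Because the labels leave the background of the CA lines open, list tests against aba2-1 mock were added after the data were seen. Relative to aba2-1 mock, ABA-induced markers were higher as a group in all 4 lines, with medians of 0.85 in the line labelled PYR1 CA (adjusted p = 9e-12), 0.85 in PYL4 CA (adjusted p = 3.3e-15), 0.57 in PYL5 CA (adjusted p = 1e-10) and 0.31 in PYL6 CA (adjusted p = 2.2e-07). These passed with an estimated correlation as well (adjusted p of 0.013, 0.013, 0.015 and 0.043). Col-0 mock itself lay above aba2-1 mock by a median of 0.29 for this list, close to the value in PYL6 CA. KIN1 rose in each line, by 1.32, 2.32, 1.36 and 1.21, and RAB18 rose by 1.49, 2.36 and 1.5 in the line labelled PYR1 CA, PYL4 CA and PYL6 CA, with 0.99 in PYL5 CA (adjusted p = 0.13) not passing. Col-0 mock lay above aba2-1 mock by 2.4 for KIN1, more than any line, and by 0.49 for RAB18 (adjusted p = 0.77). Members called numbered 6, 9, 3 and 3. Adjusted over the list alone, 16, 18, 12 and 3 were higher, with 1 lower (RD26) in the line labelled PYR1 CA. In PYL4 CA hypoxia markers were higher too (median 1.46, adjusted p = 6.4e-09), with PDC1, LBD41, PGB1, PCO1 and PCO2 called and 6 higher and 1 lower adjusted over the list alone; Col-0 mock lay 0.7 above aba2-1 mock for this list. These genes were named after their values were seen. All lines were compared with the same 3 aba2-1 mock libraries, so their results are not independent.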

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

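The interaction tests and the splits of samples were planned, as were the estimated correlations; the fit with the spread weighted by group was chosen only after the results were seen. No technical explanation was weighed for the results of this part.

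The response to 50 nM ABA differed between aba2-1 and Col-0 at 431 genes by the test of the interaction itself. ABCG14 (-1.68), AT3G50010 (-2.11), MDHAR (-1.57) and AT1G05700 (-2.67) responded more negatively in aba2-1 and CYP71A19 (2.83) more positively, on the log2 scale. These 5 calls held under each alternative setting and without each library. Without 1 library the count ran from 139 (Col-0 mock replicate 2) to 3338 (aba2-1 50 nM ABA replicate 3), and was 974 with DESeq2, 130 in a fit on the groups compared alone and 193 with the spread weighted by group. Of the 431 genes, 128 responded more positively and 303 more negatively in aba2-1; without aba2-1 50 nM ABA replicate 3 the majority turned, with 1802 and 1536.

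By list, the interaction at 50 nM was positive for ABA-induced markers (adjusted p = 8.9e-18; RAB18 1.94, KIN1 2.71, ATHB7 2.11), clade A PP2C phosphatases (adjusted p = 2.2e-06; HAI1 2.95), SnRK2 kinases with ABA bZIP/ABI factors (adjusted p = 0.0022; ABF3 1.14) and guard cell markers (adjusted p = 0.016, no member called). It was negative for PYR/PYL receptors (adjusted p = 0.0086; PYL4 -1.35, PYL5 -1.55) and hypoxia markers (adjusted p = 0.039; adjusted p = 0.36 with an estimated correlation; HRE1 -1.63). Apart from PYL4 and PYL5, these genes were named after their values were seen; the call of RAB18 was lost without Col-0 mock replicate 2 (adjusted p = 0.11), in a fit on the groups compared alone (adjusted p = 0.087) and with the spread weighted by group (adjusted p = 0.059), and that of HRE1 without Col-0 mock replicate 1 (adjusted p = 0.081). At 10 nM it was positive for cell cycle markers (adjusted p = 0.0018; adjusted p = 0.19 with an estimated correlation) and negative for the circadian clock (adjusted p = 0.0069; adjusted p = 0.2 with an estimated correlation), with no member called.

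MCCA-NOS, an unlocated row that no comparison uses, held 11291 to 37882 reads in the 12 libraries of the CA lines. It was listed at 0 in 12 of the 16 others, among them both Col-0 mock libraries and all 3 aba2-1 mock libraries, and held 5 reads in aba2-1 10 nM ABA replicate 2 and 164, 20 and 7 reads in aba2-1 50 nM ABA replicates 1, 2 and 3.

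Other splits of the same samples were counted for the comparisons of groups of 3. For 10 nM ABA in aba2-1, 1 of 10 splits, the real one, gave as many genes as the 205 called, and the highest other gave 0. For 50 nM it was again 1 of 10, with 5210 genes against 441 in the highest other. Between the doses in aba2-1, 2 of 10 splits gave as many as the 2430 called, and the highest other gave 2908; it placed aba2-1 50 nM ABA replicate 3 with replicates 1 and 2 of the 10 nM group. The splits are too few for a share under 0.05 in these comparisons. Among the 4 CA lines, 1 of 100 splits, the real one, gave as many as the 706 called. The highest other gave 488.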

How the results depend on the processing

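A pseudocount of 5, TMM rescaling, a spread weighted by group and fits without 3 libraries were chosen only after the data were seen. So was the block in the set tests. The edgeR test with TMM had been planned as the main test. Of 8618 alternative values for 520 named gene and comparison pairs, 7877 counted as the same, uncalled turns included. Calls were lost in 447, gained in 275 and turned in 19. Of the 183 calls among these pairs, 173 remained with edgeR, 177 with DESeq2, 129 in fits on only the groups compared and 161 with the spread weighted by group. The counts with edgeR, other filters, another pseudocount and TMM rescaling stayed within 1.5 times those reported. The cause was not tested for any shift below, except that fits on fewer groups estimate the spread from fewer samples.

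DESeq2 called 259 genes for aba2-1 against Col-0 mock (124 reported), 28 and 445 for 10 and 50 nM ABA in Col-0 (6 and 213) and 6 between those doses (0). It called 1082, 700, 781 and 108 for the lines labelled PYR1, PYL4, PYL5 and PYL6 CA (591, 302, 334 and 33), 3 and 974 for the interactions at 10 and 50 nM (0 and 431) and 1790 among the CA lines (706). Fits on only the groups compared gave, in that order, 363, 441, 929, 10, then 1561, 1857, 13 and 512 for the lines, 6 and 130 for the interactions, and, in aba2-1, 543 for 50 nM (5210) and 6 between the doses (2430). With the spread weighted by group the counts were 842, 374, 1464 and 46, then 3693, 2882, 88 and 1489 for the lines, 5 and 193 for the interactions, 2582 among the lines, and 1410 and 75 in aba2-1. Without the 3 doubtful libraries they were 334 for aba2-1, 504 for Col-0 at 50 nM, 2903 and 565 in aba2-1, 1363, 847, 732 and 103 for the lines and 1222 among them. The split of calls moved for PYL4 CA from 256 higher and 46 lower to 1274 and 583 on only the groups compared, 1829 and 1053 weighted by group, and 627 and 220 without the 3 libraries. For the line labelled PYR1 CA it moved from 443 and 148 to 896 and 665 on only the groups compared and 2253 and 1440 weighted by group. On only the groups compared, aba2-1 against Col-0 mock went from 65 and 59 to 235 and 128. Weighted by group, Col-0 at 50 nM went from 166 and 47 to 930 and 534, PYL5 CA from 213 and 121 to 46 and 42, and the doses in aba2-1 from 1279 and 1151 to 28 and 47; of the 193 interaction calls at 50 nM 92 were positive (128 of 431 reported). Between the doses in aba2-1, edgeR with TMM gave 1499 higher and 760 lower. With an estimated correlation 37 of 208 list tests passed (28 higher, 9 lower) in place of 83 (53 and 30), and 0 of 10 set tests in place of 6.

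With aba2-1 mock as the reference the counts for the lines were 242, 522, 33 and 25. Of the 78 named calls in the lines, 20 remained, 42 were lost and 16 turned, and of 209 named genes not called 10 gained a call. The log2 differences that turned, with those of VSP2 in PYL4 CA and KIN1 and VSP2 in PYL6 CA, which were called only against aba2-1 mock, were HEI10 -0.04, CYP71A19 0.15, AT2G05510 0.19, LTP3 0.18 and VSP2 0.47 in the line labelled PYR1 CA; MRD1 -0.01 and VSP2 2.12 in PYL4 CA; MRD1 -0.13, UGT76E12 -0.21, AT3G53980 0.03, VSP2 0.28, AT2G16005 0.12, CYP71A19 0.34 and TIP2;3 0.25 in PYL5 CA; and AT2G05510 1.11, AT2G16005 1.04, CYP71A19 1.21, KIN1 1.21 and VSP2 1.53 in PYL6 CA. KIN1, named after its values were seen and not counted here, turned from -1.08 to 1.32 in the line labelled PYR1 CA and from -1.05 to 1.36 in PYL5 CA, called on both sides.

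Leaving out 1 library at a time gave 33 (without Col-0 mock replicate 1) to 115 genes for aba2-1 against Col-0 mock. It gave 1 (without Col-0 mock replicate 2 or Col-0 10 nM ABA replicate 3) to 3 and 25 (without Col-0 mock replicate 2) to 192 for 10 and 50 nM ABA in Col-0, and 0 throughout between them. In aba2-1 it gave 99 (without mock replicate 1) to 150 at 10 nM, 2086 to 9272 at 50 nM and 485 to 8230 between the doses, the extremes without 50 nM replicates 2 and 3. For the lines it gave 42 (without Col-0 mock replicate 2) to 537 for PYR1, 10 (without Col-0 mock replicate 1) to 291 for PYL4, 29 (without Col-0 mock replicate 1) to 1137 (without PYL5 CA replicate 2) for PYL5 and 12 (without Col-0 mock replicate 1) to 26 for PYL6. Among the lines it gave 296 (without PYL6 CA replicate 3) to 1146 (without PYL5 CA replicate 1), and for the interactions 0 at 10 nM and 139 (without Col-0 mock replicate 2) to 3338 (without aba2-1 50 nM ABA replicate 3) at 50 nM. Of the 183 named calls, 104 passed without Col-0 mock replicate 2 and up to 183 without another library. Where a group of 2 lost a library, the lone sample was assumed to vary like the other groups.

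The replicate block left 128 genes for aba2-1 against Col-0 mock, 182 and 4851 for 10 and 50 nM ABA in aba2-1, 82 list tests, 6 set tests and 177 named calls, and moved no count by more than 1.5 times. It ended the list calls of photosynthesis genes in the line labelled PYR1 CA (adjusted p = 0.068) and PYL4 CA (adjusted p = 0.065), and hypoxia markers passed in PYL4 CA (adjusted p = 0.039). The numbers do not pair the samples: deviations of 117 same-numbered pairs had a median correlation across genes of 0.002, 18 pairs lay over 0.1, and 9 of 28 samples correlated best with their own number. List tests with size factors of the kind planned were not run separately, since the deposited values already carry such factors. Depth limits aba2-1 10 nM ABA replicate 3 most, with 3.77 M nuclear reads; without it 141 genes were called at 10 nM (205 reported).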

Other observations

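Tests of the gene sets from Col-0 and from aba2-1 at 10 nM ABA, of nearness to aba2-1, of the genes outside the chromosome 1 region set against Col-0 and of a correlation between libraries were chosen only after the data were seen; the tests of shared control libraries, of the chromosome 1 region by its share, of GC content with length, and of depth were written down first.

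The 166 genes higher in Col-0 at 50 nM ABA were followed in the mock-treated CA lines against aba2-1 mock, a comparison that shares no library with the call. In PYL4 CA they were higher (median log2 0.58, 90.4% of genes with the same sign, adjusted p = 6.7e-44; adjusted p = 0.00076 with an estimated correlation), and 46 of them were also called higher there. In the line labelled PYR1 CA they were also higher (median 0.5, 86.1%, adjusted p = 4.3e-27; adjusted p = 0.0052 with an estimated correlation), with 23 called against 1.72 for independent lists. In PYL5 CA the median was 0.3 (adjusted p = 3.2e-11; adjusted p = 0.061 with an estimated correlation) and in PYL6 CA -0.01 (adjusted p = 0.46). Col-0 mock lay at a median of -0.27 against aba2-1 mock for these genes, but its libraries entered the call, which draws that value down. Differences between the lines in this response were not tested. The 47 genes lower in Col-0 were lower in PYL4 CA (median -0.22, adjusted p = 3.2e-11) and higher in PYL6 CA (median 0.12, adjusted p = 0.00021; adjusted p = 0.026 with an estimated correlation).

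Genes from the response of aba2-1 to 10 nM ABA gave another view. The 106 higher ones were higher in Col-0 at 50 nM ABA (median 0.51, adjusted p = 4e-44; adjusted p = 1.6e-06 with an estimated correlation), with 29 called against 0.837 for independent lists, and in PYL4 CA against Col-0 mock (median 0.31, adjusted p = 6.6e-15; adjusted p = 0.00084 with an estimated correlation), with 18 called against 1.29. The 99 lower ones were higher in the line labelled PYR1 CA than in Col-0 mock (median 0.33, adjusted p = 3.4e-09; adjusted p = 0.033 with an estimated correlation), opposite in sign to aba2-1 at 10 nM ABA. There the 106 higher ones did not pass (adjusted p = 0.53), with 8 called higher against 2.23 for independent lists and 15 called lower against 0.746. In PYL5 CA 4 of the 106 were called higher against 1.07, and 14 lower against 0.61. The 99 lower ones were higher in PYL6 CA as well (adjusted p = 0.00056; adjusted p = 0.23 with an estimated correlation). Against aba2-1 mock, in the line labelled PYR1 CA, PR2 rose by 4.81 and the seed storage gene CRA1 by 5.41, genes named after their values were seen.

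At the 124 genes that separate aba2-1 mock from Col-0 mock, the mock-treated CA lines tended to lie with aba2-1: 80.6%, 65.3%, 86.3% and 68.5% of these genes lay nearer aba2-1 10 nM ABA than Col-0 10 nM ABA, libraries not used for the call, in the lines labelled PYR1, PYL4, PYL5 and PYL6 CA. The pattern did not rest on the genes of the ABA2 region, since without the 7 of 124 genes within 2 Mb of ABA2 the shares were 79.5%, 65%, 85.5% and 66.7%, the lowest 38.5 percentage points above Col-0 50 nM ABA (26.5%). A difference in that region, which holds ABA2 itself, could still act on genes elsewhere, and the bound of 75% in each line set beforehand for excluding it was not met. The shared Col-0 mock libraries helped choose the 124 genes but did not enter their shares. At 69 genes called between the 10 nM groups, 79.7%, 85.5%, 95.7% and 88.4% kept the sign of aba2-1. This argues against chance values of those libraries alone, though the lowest fell just short of the bound of 80% set beforehand for exclusion. An aba2-1 background, which the labels leave open, is not decided by these shares, since an active receptor may move ABA genes back towards Col-0 and aba2-1 50 nM ABA itself lay at 60.7% without the region. The background, the region and an effect of the transgenes stay open.

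The libraries of aba2-1 50 nM ABA and of PYL5 CA spread more widely than those of other groups. Trends with GC content and gene length and library depth are each excluded as the whole cause, since removal of the trends left median gene SDs of 0.307 and 0.239, the lower 1.61 times the next highest group (0.149), and thinning every library to the shallowest left 0.37 and 0.338, the lower 1.74 times the next (0.194). Unequal uptake of added ABA cannot account for PYL5 CA, by design, since none was added there. In aba2-1 50 nM ABA it stays open: the deviations of its replicate 2 correlated across 21023 genes, which are not independent, with those of PYL5 CA replicate 3 (r = 0.52), but these libraries were picked for standing apart to the same side of the first component, so the correlation decides nothing. A difference in handling or growth could remain in both groups, and no biological explanation was tested.

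In the Col-0 libraries MRD1 and HEI10 took different levels in replicates of a single group. MRD1 held 11.59 and 21.69 normalised reads in mock replicates 1 and 2, 177 and 6.576 in 10 nM replicates 2 and 3, and 153.9, 380.2 and 9.149 in 50 nM replicates 1, 2 and 3. HEI10 held 29.95 and 47.15, 113.2 and 37.27, and 112.2, 132.6 and 36.6 in the same libraries. Across aba2-1 and the CA lines HEI10 held 303.1 to 536.3 and MRD1 570.3 to 898.6. No explanation was tested. Whether the Col-0 seed was a mixture of stocks stays open, and each comparison with Col-0 rests on these libraries.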
